A study of Homo sapiens with 8 samples.

How the data were processed

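Total RNA of NCI-H1975 cells was measured on 8 Affymetrix Human Genome U133 Plus 2.0 arrays, 1 array for each combination of L-histidinol (absent or 2 mM) with vehicle, 10 nM osimertinib, 1 µM alpelisib or both drugs, all after 24 hours. Per the labels' protocols, cells grew in RPMI1640 with 10% serum, and biotinylated cRNA was made from 100 ng of RNA extracted with RNeasy columns. The deposited values are linear signal intensity per probe set, which the authors made with RMA and the affy package per the submitters' processing notes. The versions of RMA and affy are not given in the sources used here. The design written before the files were opened foresaw log2 values, and since the table is linear the log2 of each intensity was taken first. Quartiles of intensity lay between 7.47 and 7.66 and between 101 and 106 on every array, and no further scaling was applied.

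Of the probe sets, 62 controls were set aside, 41091 carried exactly 1 gene symbol, 1801 several and 11721 none. Probe sets with several symbols or none were left out of the gene tests. Entrez identifiers of 41037 probe sets matched the RefSeq gene table, and 0 symbols had to be updated. For each of 19775 genes, the probe set with the highest mean over the 8 arrays was used, and 9252 genes had a single probe set. No filter on dim probe sets was applied, except that gene families described among the other observations were counted over members with a mean log2 of at least 5. No genome or coordinates were used.

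Differences were fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0) as the sum of an L-histidinol effect and a drug treatment of 4 levels, with moderated variances that follow mean intensity (3 residual degrees of freedom, 8.08 prior degrees of freedom). Contrasts of this fit gave L-histidinol over 4 array pairs, each drug treatment against vehicle, the combination against each single drug, osimertinib against alpelisib, and the departure of the combination from the sum of the single drugs. The interactions of L-histidinol with each drug came from a fit with all 2-way terms and 1 residual degree of freedom, whose prior was estimated at 103 degrees of freedom. P-values were adjusted by Benjamini and Hochberg over all genes, and genes were called at an adjusted p below 0.05. A 2-fold change is 1 log2 unit.

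Fixed gene lists, 21 in number, were written before the files were opened, and 303 of their 327 members were measured. The others had no probe set with their symbol alone in the probe table used here. Each list was compared with all other genes by camera of limma at its preset correlation between genes of 0.01, adjusted over the lists of a comparison, and camera with an estimated correlation and fry were run as alternatives. With an estimated correlation camera tests at the residual degrees of freedom, 3 or 1 here, so a call is hardly possible. At the preset correlation its degrees of freedom follow the number of genes, and list members are treated as nearly independent. Its p-values are then not limited by the number of arrays and can be very small. Members were counted as called after adjustment over all genes and after adjustment over their list alone. For differences between single arrays, list medians were placed among 10000 random lists of the same size and matched expression. Correlations across genes were taken only between array pairs that share no array.

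Genes were named by a rule fixed beforehand. In each comparison of a treatment with vehicle it took the 8 largest rises and 8 largest falls. In each other comparison it took the 5 largest each way. Both were taken among called genes with the same sign in every array pair. Up to 4 members of each list by size of change and 13 genes fixed in advance were added. PIK3CA, also fixed in advance, was left out when the rule was applied. Which genes of this set are printed was decided after their values had been seen, and the 6 genes called in the interaction of the drugs were all named because they were few. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 and drawn with matplotlib 3.10.9.

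The scripts were tested on simulated data of 19775 genes with 200 changed genes. Noise was drawn independently for each gene from the prior of the additive fit, without shifts of whole arrays. The recovered and false shares therefore check the scripts and do not carry over to the real calls. For L-histidinol 83.5%, 100% and 100% of changes of 0.5, 1 and 2 log2 units were recovered, with 4.57%, 7.83% and 4.31% of the calls false. For osimertinib the recovered shares were 35.0%, 94.5% and 100% and the false shares 4.11%, 3.57% and 3.85%. For the interaction of osimertinib with alpelisib they were 0%, 75% and 100%, with 0%, 4.46% and 6.10% of the calls false. The interaction of L-histidinol with osimertinib recovered 27.5%, 93.5% and 100%, but with far larger false shares, and holding the prior at that of the additive fit recovered 0%, 62.5% and 99.5% with 0, 4 and 6 false calls. This held prior was added as an alternative after the interaction results had been seen.

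The results were also computed with the mean of all probe sets of a gene, removal of probe sets whose names mark possible cross-hybridization, a mean log2 of at least 5, centring of arrays on their medians, cyclic loess, variances without the trend or with a robust prior, other codings of the model, and leaving out each array in turn. Matching of cell cultures, batches and hybridization dates between arrays was not given in the sources used here, so none was fitted.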

Results

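The series profiled NCI-H1975 cells on 8 Affymetrix 3′ expression arrays. NCI-H1975 is an established human lung adenocarcinoma line whose growth is driven by a mutant EGFR receptor. Cells were exposed for 24 hours to vehicle, to 10 nM osimertinib, to 1 µM alpelisib or to both drugs, and each of these 4 treatments was given without and with 2 mM L-histidinol. Osimertinib is a covalent inhibitor of mutant EGFR, and alpelisib inhibits the alpha catalytic subunit of PI3K. L-histidinol is a histidine analog that competes for histidyl-tRNA synthetase and is used to mimic histidine starvation. Each of the 8 conditions had 1 array, so L-histidinol was compared over 4 pairs of arrays that shared a drug treatment, and each drug treatment over 2 arrays against 2.

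After the authors' normalization the median intensity per array lay between 21.8 and 22.4, and the arrays correlated with each other at r = 0.974 to 0.996 across genes. The first principal component held 63.5% of the variance and ordered the drug treatments from vehicle (-39.5 and -36.0) through alpelisib (-14.6 and -11.1) and osimertinib (14.2 and 12.6) to the combination (41.2 and 33.2). The second held 16.9% and separated the 4 arrays without L-histidinol (-17.9 to -9.30) from the 4 arrays with it (11.8 to 18.2). Each gene was represented by 1 probe set, and 19775 genes were tested. Camera's p-values for lists at the preset correlation treat genes as nearly independent and are not limited by the number of arrays. Effects are fitted log2 differences ± standard error, and limma's adjusted p-values for single genes measure only the spread between these arrays. That spread is the departure from additive effects of L-histidinol and drug, so it holds any real interaction as well as noise, and the number of arrays limits the precision. Differences between single arrays have no replicate check.

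L-histidinol raised the transcripts of amino acid supply and of the integrated stress response (ISR), the program run by the transcription factor ATF4. Asparagine synthetase, ASNS, rose by 2.02 ± 0.12 on the log2 scale (adjusted p = 3.0e-06), and the mitochondrial folate enzyme ALDH1L2 rose by 2.08 ± 0.21 (adjusted p = 1.1e-04). The ASNS value rests on a probe set whose name marks possible cross-hybridization, and with such probe sets left out another one gave 0.08 for ASNS (adjusted p = 0.695). The serine synthesis enzymes PSAT1 (1.69 ± 0.05) and PHGDH (1.54 ± 0.06) rose in all 4 drug backgrounds, as did the glutathione-degrading enzyme CHAC1 (1.77 ± 0.14). Sterol synthesis genes and DNA replication genes fell, led by HMGCS1 (-0.97 ± 0.10) and thymidylate synthase, TYMS (-0.95 ± 0.12). In all, 4069 genes were called, 2256 higher and 1813 lower, and 49 of them changed at least 2-fold, 38 upward and 11 downward.

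Of the 22 measured ISR stress genes, 19 rose and 1 fell, and 21 were called when adjusted over the list alone. Their median change was 0.84 (camera adjusted p = 3.95e-14; adjusted p = 0.307 with an estimated correlation). ATF4 itself rose by 0.82 ± 0.06 (adjusted p = 2.1e-05), its target DDIT3 by 0.40 ± 0.06 and the pseudokinase TRIB3 by 1.12 ± 0.09. The stress-induced factor NUPR1 (1.77 ± 0.18), the mTORC1 inhibitor DDIT4 (1.55 ± 0.06) and the secreted cytokine GDF15 (1.44 ± 0.19) were among the strongest. Without the probe sets marked for possible cross-hybridization GDF15 was not called (0.12, adjusted p = 0.454). Amino acid synthesis genes rose in 11 of 12 cases, also over the list alone, with a median of 0.85 (camera adjusted p = 4.9e-12; adjusted p = 0.244 with an estimated correlation). Amino acid transporters rose in 10 of 11 cases by either adjustment, median 0.90 (camera adjusted p = 5.8e-12; adjusted p = 0.274 with an estimated correlation). The cystine importer SLC7A11 led them at 1.56 ± 0.08, followed by SLC3A2 (1.11 ± 0.06), the neutral amino acid carrier SLC7A5 (1.08 ± 0.04) and SLC38A1 (1.05 ± 0.06).

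Aminoacyl-tRNA synthetases, which load amino acids onto tRNAs, rose in 11 of 17 cases by either adjustment, and their median change was 0.56 (camera adjusted p = 1.7e-07; adjusted p = 0.244 with an estimated correlation). The tyrosine enzyme YARS1 rose by 0.82 ± 0.05, WARS1 by 0.78 ± 0.06, AARS1 by 0.72 ± 0.06 and SARS1 by 0.70 ± 0.05. The histidine enzyme HARS1, the target of L-histidinol, differed by -0.08 ± 0.05 and was not called (adjusted p = 0.29). Chaperones of the endoplasmic reticulum and the unfolded protein response split evenly, with 5 of 16 higher and 5 lower by either adjustment (camera adjusted p = 0.668). XBP1 rose by 0.52 ± 0.09 and SEL1L by 0.46 ± 0.05, whereas the chaperone CRELD2 fell by 0.56 on the log2 scale and SDF2L1 by 0.49. With the mean of probe sets XBP1 was not called (0.25, adjusted p = 0.0546).

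Genes of sterol and fatty acid synthesis fell in 15 of 19 cases (16 over the list alone) with none higher, median -0.36 (camera adjusted p = 1.7e-09; adjusted p = 0.307 with an estimated correlation). Besides HMGCS1, the reductase DHCR7 changed by -0.80 ± 0.11, the epoxidase SQLE by -0.77 ± 0.07 and the isomerase IDI1 by -0.62 ± 0.06. The IDI1 value changed sign when probe sets marked for possible cross-hybridization were left out. G1/S and DNA replication genes fell in 15 of 21 cases (17 over the list alone), median -0.42 (camera adjusted p = 7.9e-09; adjusted p = 0.385 with an estimated correlation). With both drugs present the median L-histidinol response of this list was only -0.03. Cyclin E2, CCNE2, changed by -0.74 ± 0.15, GINS2 by -0.70 ± 0.13 and MCM5 by -0.68 ± 0.11. Without the marked probe sets GINS2 was not called (-0.07, adjusted p = 0.674). Of 20 G2/M and mitosis genes 2 fell by either adjustment (0 to 6 with 1 array left out), the kinesin KIF11 (-0.54 ± 0.12) and the kinase AURKB (-0.47 ± 0.11), the former not called without either alpelisib array and the latter not with the same sign in every array pair and not called with the mean of probe sets (-0.31, adjusted p = 0.152) or when any 1 of the 4 arrays with a single drug was left out, and the list was not called (camera adjusted p = 0.321). MYC rose by 0.60 ± 0.05 and 5 of 13 genes of its ribosome biogenesis list rose by either adjustment, with a median of 0.13 (camera adjusted p = 8.2e-03; adjusted p = 0.579 with an estimated correlation). The polymerase I subunit POLR1B (0.38 ± 0.06) was 1 of them. The median response of this list was -0.04 in vehicle, 0.15 with either single drug and 0.33 with both.

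Smaller shifts followed in other lists. Interferon response genes rose in 9 of 17 cases (11 over the list alone), median 0.25 (camera adjusted p = 2.2e-04; adjusted p = 0.403 with an estimated correlation), among them the antiviral genes IFI44L (0.90 ± 0.16) and MX1 (0.79 ± 0.16). FOXO targets and PI3K feedback genes rose in 8 of 19 cases (9 over the list alone), median 0.16 (camera adjusted p = 1.3e-03; adjusted p = 0.307 with an estimated correlation), led by the insulin receptor substrate IRS2 at 0.87 ± 0.08. Lysosome and autophagy genes rose in 8 of 15 cases and 1 fell (9 and 1 over the list alone), median 0.16 (camera adjusted p = 3.3e-03; adjusted p = 0.326 with an estimated correlation). The autophagy receptor SQSTM1 rose by 0.51 ± 0.06, a value that did not hold with its other probe sets. Epithelial genes fell in 5 of 12 cases (over the list alone 5 fell and 1 rose), median -0.09 (camera adjusted p = 0.0438; adjusted p = 0.307 with an estimated correlation), including the lung transcription factor NKX2-1 (-0.62 ± 0.08) and the keratin KRT18 (-0.53 ± 0.05).

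The remaining lists were not called for L-histidinol. ERK output genes, which follow MAP kinase activity, were higher in 6 and lower in 2 of 18 cases (9 and 2 over the list alone; camera adjusted p = 0.0605). The BCL2 family and death receptor genes were higher in 3 of 10 (4 over the list alone; camera adjusted p = 0.0605), including the BH3-only genes HRK (0.62 ± 0.08) and PMAIP1 (0.60 ± 0.05). Receptor tyrosine kinases were higher in 2 and lower in 4 of 11 cases (2 and 5 over the list alone; camera adjusted p = 0.11), with FGFR3 at -0.79 ± 0.10. For p53 targets 4 of 9 were higher and 1 lower (4 and 2 over the list alone; camera adjusted p = 0.206), and for glycolysis and hypoxia genes 2 of 14 were higher and 4 lower (2 and 5 over the list alone; camera adjusted p = 0.508), VEGFA rising by 0.79 ± 0.08. The glycolysis list had a median of -0.07 against a mean of 0.01, and its test pointed down. The EGFR ligand list gave 1 rise and 1 fall among its 5 genes by either adjustment (camera adjusted p = 0.855). Mesenchymal genes gave 1 rise and 2 falls among 10 (2 and 2 over the list alone), with a median of 0.01 against a mean of -0.04 (camera adjusted p = 0.905), the matrix protein SPARC falling by 0.79 on the log2 scale. Of the 12 markers of fibroblasts, blood and endothelial cells 1 fell by either adjustment, the collagen COL1A1 (-0.41 ± 0.06; camera adjusted p = 0.314 for the list). COL1A1 lay at a mean log2 intensity of 9.14, while PTPRC, COL3A1 and LUM lay at 2.82, 2.83 and 2.17.

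Single genes with the largest changes outside these lists included CSTA, a cystatin of the epidermal barrier (1.98 ± 0.15), the mitochondrial enzyme PCK2 (1.91 ± 0.12) and the lysosomal membrane protein LAMP3 (1.60 ± 0.18). The largest falls were those of the chloride channel protein CLIC3 (-1.30 ± 0.09), ZBED2 (-1.29 ± 0.15), the matrix protein MGP (-1.27 ± 0.16), the alkaline phosphatase ALPP (-1.26 ± 0.11), creatine kinase CKB (-1.22 ± 0.06), VTCN1 (-1.20 ± 0.16), involucrin, IVL (-1.12 ± 0.13), and CYP27C1 (-1.08 ± 0.16). MGP was not called without the marked probe sets (-0.09, adjusted p = 0.728). The intensity ratio of the ACTB control probe sets at the 3′ and 5′ ends, a measure of RNA quality, lay at 1.04 to 1.07 without L-histidinol and at 1.10 to 1.15 with it, beside a GAPDH ratio of 0.966 to 1.01 over all arrays. Leaving out the osimertinib array or its L-histidinol partner lowered the number of called genes to 2160 and 2168. Without the osimertinib array 3 interferon response genes, 3 lysosome and autophagy genes, 5 FOXO targets and 3 MYC and ribosome biogenesis genes were called higher, and without the alpelisib array 9 G1/S genes and 0 G2/M genes were called lower. The alpelisib array left out also gave 2 p53 targets higher and 1 glycolysis gene lower, and the vehicle array left out gave 3 ERK output genes higher.

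**Figure D1:**
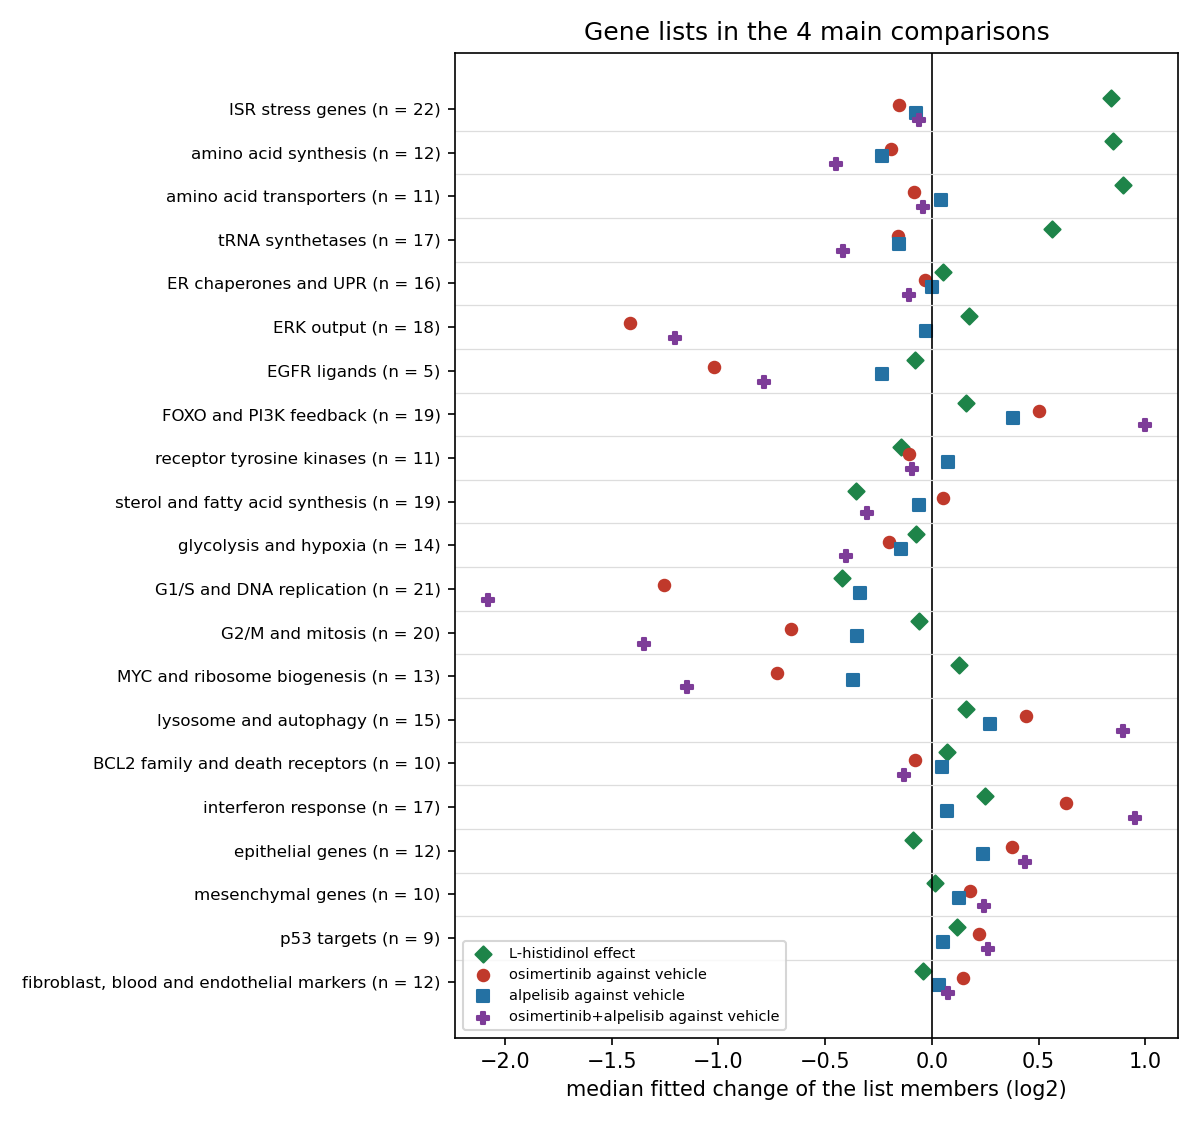
Median fitted change of each fixed gene list, in log2 units on the horizontal axis, for L-histidinol (green diamonds) and for osimertinib (red circles), alpelisib (blue squares) and both drugs (purple crosses) against vehicle, with the number of measured genes in brackets. The ISR, amino acid and tRNA synthetase lists stand to the right for L-histidinol, with medians of 0.56 to 0.90, and the ERK output list stands at -1.41 for osimertinib and -1.21 for both drugs. The small alpelisib medians of the amino acid transporter, endoplasmic reticulum, receptor tyrosine kinase, BCL2 family, interferon, p53 and other-cell lists, the osimertinib median of the sterol list and the combination median of the other-cell list change sign when arrays are centred or scaled by loess.

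Osimertinib against vehicle asked what inhibition of mutant EGFR does in these cells. Transcripts that report ERK signaling fell furthest. The ERK phosphatase DUSP6 fell by 4.0 ± 0.18 on the log2 scale (adjusted p = 1.8e-07), the ETS factor ETV5 by -3.27 ± 0.17, the AP-1 subunit FOSL1 by -2.89 ± 0.09, cyclin D1, CCND1, by -1.85 ± 0.17 and the feedback inhibitor SPRY4 by -1.42 ± 0.19. Replication and mitosis genes fell as well, whereas interferon response genes, FOXO targets and lysosomal genes rose. Called genes numbered 6011, 3246 higher and 2765 lower, and 554 changed at least 2-fold. Without the osimertinib array 3755 were called. When each array was instead centred on its median the split was 2289 higher and 4123 lower.

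Of 18 ERK output genes 17 fell by either adjustment, median -1.41 (camera adjusted p = 1.4e-16; adjusted p = 0.103 with an estimated correlation). Of the 5 genes of the EGFR ligand list 3 fell by either adjustment, TGFA by 1.80, EREG by 1.29 and NRG1 by 1.02 on the log2 scale. NRG1 encodes a ligand of ERBB3 and ERBB4 and not of EGFR itself. The list was called (camera adjusted p = 0.0154; adjusted p = 0.306 with an estimated correlation). NRG1 was not called without the marked probe sets (-0.13, adjusted p = 0.651). EGFR changed by -0.54 ± 0.07, while its partners ERBB2 (0.96 ± 0.07) and ERBB3 (1.17 ± 0.07) rose. All 21 G1/S and DNA replication genes fell by either adjustment, median -1.25 (camera adjusted p = 1.4e-15; adjusted p = 0.306 with an estimated correlation), led by the replication factor MCM10 (-2.03 ± 0.19) and CDC6 (-1.79 ± 0.18). G2/M and mitosis genes fell in 18 of 20 cases (19 over the list alone), median -0.66 (camera adjusted p = 6.6e-08; adjusted p = 0.429 with an estimated correlation), and 8 of them were called when the osimertinib array was left out. All 13 genes of MYC and ribosome biogenesis fell by either adjustment, median -0.72 (camera adjusted p = 4.5e-09; adjusted p = 0.306 with an estimated correlation). MYC changed by -0.64 ± 0.07 and the ribosome assembly factor NOP16 by -1.02 ± 0.13.

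FOXO targets and PI3K feedback genes rose in 14 of 19 cases and 1 fell by either adjustment, median 0.50 (camera adjusted p = 7.3e-06; adjusted p = 0.259 with an estimated correlation). The atypical cyclin CCNG2 rose by 1.61 ± 0.08 and the death ligand TNFSF10 by 1.34 ± 0.14. Interferon response genes rose in 15 of 17 cases and 1 fell (16 and 1 over the list alone), median 0.63 (camera adjusted p = 5.8e-06; adjusted p = 0.346 with an estimated correlation). IFITM1 rose by 1.39 ± 0.11 and MX1 by 1.30 ± 0.23. Interferon genes called higher numbered 9 without the osimertinib array with L-histidinol. Lysosome and autophagy genes rose in 11 of 15 cases and 1 fell (13 and 1 over the list alone), median 0.44 (camera adjusted p = 6.9e-05; adjusted p = 0.306 with an estimated correlation). The autophagy kinase ULK1 rose by 1.28 ± 0.09 and the protease CTSD by 1.01 ± 0.10. Epithelial genes rose in 8 of 12 cases (over the list alone 10 rose and 1 fell), median 0.38 (camera adjusted p = 1.7e-03; adjusted p = 0.259 with an estimated correlation). NKX2-1 rose by 1.35 ± 0.12 and E-cadherin, CDH1, by 0.59 ± 0.06. Among the markers of other cell types 4 of 12 rose, COL1A1 by 1.34 ± 0.09, and the list was not called (camera adjusted p = 0.112).

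Glycolysis and hypoxia genes fell in 7 of 14 cases and 1 rose (9 and 2 over the list alone), median -0.20 (camera adjusted p = 0.0110; adjusted p = 0.301 with an estimated correlation), hexokinase HK2 falling by 0.80 on the log2 scale. Aminoacyl-tRNA synthetases fell in 8 of 17 cases and 2 rose by either adjustment, median -0.16 (camera adjusted p = 0.0136; adjusted p = 0.306 with an estimated correlation). FARSA changed by -0.78 ± 0.11 and HARS1 by -0.53 ± 0.07. Without the osimertinib array 5 synthetases were called lower. The ISR list was not called (camera adjusted p = 0.951), and its median of -0.15 differed in sign from its mean of 0.13. Its members went both ways: ATF4 (0.05 ± 0.09), ASNS of the synthesis list (-0.06 ± 0.17) and CHAC1 (-0.26 ± 0.20) were not called, while NUPR1 (1.91 ± 0.25) and the ubiquitin ligase adaptor KLHL24 (1.97 ± 0.17) rose. Without the vehicle array ASNS (-0.44) and CHAC1 (-0.68) were called lower, and CHAC1 was called with all 2-way terms. Without the vehicle array with L-histidinol their signs turned (0.32 and 0.16) and neither was called, so the direction of both was left open. With 1 array left out 1 to 8 ISR genes were called lower. BMF (1.19 ± 0.11) and BCL2L11 (0.66 ± 0.07), which encode pro-apoptotic BH3-only proteins, rose, and the anti-apoptotic BCL2L1 changed by -0.78 ± 0.10. With the mean of probe sets BCL2L11 was not called (0.11, adjusted p = 0.31). The largest single rises were those of CLIC3 (3.29 ± 0.13), TMT1A (2.97 ± 0.19), the interferon-inducible GTPase GBP2 (2.71 ± 0.12), the matricellular protein CCN5 (2.67 ± 0.07), MAP7D2 (2.60 ± 0.09), TP53INP1 (2.53 ± 0.12), the aldo-keto reductase AKR1B10 (2.47 ± 0.12) and NFE2 (2.39 ± 0.10). TMT1A rested on a probe set marked for possible cross-hybridization, and without it the sign turned, as it did for the combination. The peroxisomal oxidase ACOX2 (-2.80 ± 0.16) and the pentraxin PTX3 (-2.73 ± 0.17) were among the largest falls.

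Alpelisib against vehicle gave fewer and smaller changes, which included rises of FOXO targets and of feedback genes of PI3K. The largest rise was that of YPEL3, a growth-suppressing gene (2.13 ± 0.08, adjusted p = 5.6e-07). CCNG2 rose by 1.14 ± 0.08, IRS2 by 0.90 ± 0.12, ERBB3 by 0.86 ± 0.07 and the pyruvate dehydrogenase kinase PDK4 by 1.20 ± 0.27. Of 18 ERK output genes 1 rose, EGR1 (0.93 ± 0.25), and 1 fell, FOSL1 (-0.39 ± 0.09), by either adjustment, and both calls were lost without either alpelisib array. EGR1 fell short without the vehicle array too (0.51, adjusted p = 0.32), as did FOSL1 without the vehicle array with L-histidinol (-0.30). DUSP6 (0.21 ± 0.18), SPRY4 (-0.13 ± 0.19), CCND1 (-0.00 ± 0.17) and MYC (-0.01 ± 0.07) were not called, though DUSP6 was without the vehicle array with L-histidinol (0.58, adjusted p = 0.044). In all 2267 genes were called, 1401 higher and 866 lower, and the 58 that changed at least 2-fold were all higher. With arrays centred the split was 953 higher and 2000 lower.

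FOXO targets and PI3K feedback genes rose in 9 of 19 cases (16 over the list alone), median 0.38 (camera adjusted p = 1.8e-09; adjusted p = 0.229 with an estimated correlation). Lysosome and autophagy genes rose in 7 of 15 cases (over the list alone 10 rose and 1 fell), median 0.27 (camera adjusted p = 5.2e-05; adjusted p = 0.374 with an estimated correlation). ULK1 rose by 0.72 ± 0.09 and the protease CTSB by 0.57 ± 0.07. Epithelial genes rose in 7 of 12 cases (8 over the list alone), median 0.24 (camera adjusted p = 1.1e-04; adjusted p = 0.229 with an estimated correlation). NKX2-1 rose by 0.86 ± 0.12 and the claudin CLDN4 by 0.43 ± 0.07. MYC and ribosome biogenesis genes fell in 9 of 13 cases (12 over the list alone), median -0.37 (camera adjusted p = 5.1e-07; adjusted p = 0.488 with an estimated correlation), SRM, spermidine synthase, changing by -0.57 ± 0.07. G2/M genes fell in 3 of 20 cases (11 over the list alone; camera adjusted p = 4.3e-06; adjusted p = 0.488 with an estimated correlation). G1/S genes fell in 2 of 21 cases (11 over the list alone; camera adjusted p = 6.5e-06; adjusted p = 0.488 with an estimated correlation), and the medians were -0.35 and -0.34. Their called members were PLK1 (-0.62 ± 0.15) and CDC20 (-0.57 ± 0.12) among others in the first list, and MCM10 (-0.65 ± 0.19) and CDC25A (-0.55 ± 0.11) in the second.

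Aminoacyl-tRNA synthetases fell in 6 of 17 cases (8 over the list alone; camera adjusted p = 5.6e-04; adjusted p = 0.317 with an estimated correlation). Glycolysis and hypoxia genes fell in 2 of 14 (8 over the list alone; camera adjusted p = 2.3e-03; adjusted p = 0.269 with an estimated correlation), and amino acid synthesis genes in 6 of 12 by either adjustment (camera adjusted p = 0.0272; adjusted p = 0.488 with an estimated correlation). HK2 changed by -0.47 ± 0.08, PSAT1 by -0.38 ± 0.06 and HARS1 by -0.31 ± 0.07. Mesenchymal genes rose in 2 of 10 cases by either adjustment (camera adjusted p = 0.0483; adjusted p = 0.488 with an estimated correlation), fibronectin, FN1, by 0.56 ± 0.06, which was not called without the marked probe sets (0.45, adjusted p = 0.0959). The ERK output list was not called (camera adjusted p = 0.541). Other leading rises were those of LBH (1.97 ± 0.10), the water channel AQP3 (1.80 ± 0.19), TMEM255A (1.69 ± 0.15), BEAN1 (1.68 ± 0.27), GBP2 (1.66 ± 0.12), the autophagy lipid scramblase ATG9B (1.65 ± 0.14) and LEMD1 (1.62 ± 0.10). The largest falls were those of the histone gene H2BC11 (-0.95 ± 0.14), DDIT4 (-0.90 ± 0.09), CCDC138 (-0.83 ± 0.13), the polymerase III subunit POLR3G (-0.82 ± 0.12) and TEX15 (-0.79 ± 0.09). The number of called genes fell to 175 without the alpelisib array with L-histidinol, to 600 without the other alpelisib array and to 1171 without the vehicle array. The member counts of the alpelisib lists leaned on single arrays too. Without the alpelisib array with L-histidinol 4 FOXO targets and 0 epithelial genes were called higher and 0 MYC, G1/S or aminoacyl-tRNA synthetase genes lower. Without the other alpelisib array 2 lysosome and autophagy genes and 1 mesenchymal gene were called higher and 0 amino acid synthesis or glycolysis genes lower, and without the vehicle array 0 G2/M genes were lower. Over all arrays left out in turn the counts lower ran from 0 to 16 for G1/S, 0 to 17 for G2/M and 0 to 12 for MYC genes, and the FOXO targets higher from 4 to 12. Without the alpelisib array with L-histidinol BEAN1, CCDC138, CDC20, CDC25A, CLDN4, H2BC11, HARS1, HK2, MCM10, NKX2-1, PDK4, PLK1, POLR3G, PSAT1 and SRM were not called. Of these CDC20, HARS1, HK2, MCM10, PDK4, PLK1 and PSAT1 were not called without the other alpelisib array, CDC20, HARS1, MCM10 and PLK1 without the vehicle array, and MCM10 without the vehicle array with L-histidinol. PDK4 was called at 1.86 without the vehicle array and at 0.55 without its L-histidinol partner. With the mean of probe sets PDK4 (0.55), CLDN4 (0.24), HK2 (-0.23), MCM10 (-0.61) and PLK1 (-0.62) were not called, nor was EGR1. Without the variance trend PDK4, MCM10, PLK1, EGR1, CDC20, HARS1, PSAT1 and FOSL1 were not called, and with the robust prior MCM10, PLK1 and EGR1 were not.

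The combination of both drugs against vehicle gave the largest number of called genes of all comparisons made, 8033, with 4233 higher, 3800 lower and 1440 changed at least 2-fold. Centring the arrays turned the split to 3178 higher and 5516 lower. DNA replication genes changed by several log2 units, MCM10 by -3.46 ± 0.19 and CDC6 by -2.85 ± 0.18, and their measured list fell in 21 of 21 cases by either adjustment with a median of -2.08 (camera adjusted p = 1.9e-14; adjusted p = 0.361 with an estimated correlation). All 20 G2/M and mitosis genes fell by either adjustment, median -1.35 (camera adjusted p = 8.7e-11; adjusted p = 0.377 with an estimated correlation). AURKB changed by -2.13 ± 0.15, cyclin A2, CCNA2, by -1.84 ± 0.15 and CDK1 by -1.80 ± 0.15. FOXO targets and PI3K feedback genes rose in 17 of 19 cases and 1 fell by either adjustment, median 1.00 (camera adjusted p = 1.9e-08; adjusted p = 0.162 with an estimated correlation), TNFSF10 by 2.61 ± 0.14, PDK4 by 2.38 ± 0.27, ERBB3 by 1.94 ± 0.07 and IRS2 by 1.74 ± 0.12.

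ERK output genes fell in 15 of 18 cases (16 over the list alone), median -1.21 (camera adjusted p = 3.9e-10; adjusted p = 0.162 with an estimated correlation). FOSL1 changed by -3.65 ± 0.09 (adjusted p = 7.7e-10), DUSP6 by -3.52 ± 0.18, ETV5 by -3.12 ± 0.17 and CCND1 by -2.42 ± 0.17. All 13 MYC and ribosome biogenesis genes fell by either adjustment, median -1.15 (camera adjusted p = 1.9e-08; adjusted p = 0.365 with an estimated correlation), MYC itself by 0.62 on the log2 scale. Interferon response genes rose in 16 of 17 cases by either adjustment, median 0.95 (camera adjusted p = 7.5e-08; adjusted p = 0.361 with an estimated correlation). OAS2 rose by 2.08 ± 0.19 and the regulator IRF7 by 2.07 ± 0.14. Lysosome and autophagy genes rose in 13 of 15 cases and 1 fell by either adjustment, median 0.90 (camera adjusted p = 3.9e-06; adjusted p = 0.248 with an estimated correlation). ULK1 rose by 1.74 ± 0.09 and GABARAPL1 by 1.55 ± 0.11. Epithelial genes rose in 8 of 12 cases (9 over the list alone), median 0.44 (camera adjusted p = 6.2e-04; adjusted p = 0.218 with an estimated correlation). NKX2-1 rose by 1.90 ± 0.12. The p53 target list was called on 5 rises and 1 fall among 9 by either adjustment (camera adjusted p = 0.027; adjusted p = 0.392 with an estimated correlation), TP53INP1 rising by 3.58 ± 0.12 and the cell cycle inhibitor CDKN1A by 1.28 ± 0.11. Of the 12 markers of other cell types 3 rose, COL1A1 by 1.53 ± 0.09 (camera adjusted p = 0.197 for the list).

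Aminoacyl-tRNA synthetases fell in 12 of 17 cases and 1 rose by either adjustment, median -0.42 (camera adjusted p = 3.8e-04; adjusted p = 0.244 with an estimated correlation), VARS1 changing by -1.31 ± 0.08, FARSA by -1.20 ± 0.11 and HARS1 by -0.85 ± 0.07. Amino acid synthesis genes fell in 7 of 12 cases and 1 rose (7 and 2 over the list alone), median -0.45 (camera adjusted p = 0.0270; adjusted p = 0.377 with an estimated correlation), PSAT1 changing by -1.25 ± 0.06. Glycolysis and hypoxia genes fell in 9 of 14 cases and 1 rose (9 and 3 over the list alone), median -0.40 (camera adjusted p = 5.7e-03; adjusted p = 0.244 with an estimated correlation). The ISR list was not called (camera adjusted p = 0.704), and its median of -0.06 differed in sign from its mean of 0.24. DDIT3 rose by 0.77 ± 0.09, TRIB3 changed by -0.50 ± 0.12, and ASNS (-0.32 ± 0.17) and CHAC1 (-0.45 ± 0.20) were not called. ATF4 was called at 0.29 ± 0.09, but not after centring (0.15), with the mean of probe sets, without the variance trend, or without the vehicle array (0.14) or the combination array (0.10). ASNS and CHAC1 were called lower after centring (-0.45 and -0.59), without the vehicle array (-0.70 and -0.88), without the combination array (-0.64 and -0.76) and with all 2-way terms. Without the L-histidinol partner of either array they were not called (0.06 and -0.03 without that of vehicle). TRIB3 was not called without the vehicle array with L-histidinol (-0.28) or without the combination array with L-histidinol (-0.27). BMF (1.99 ± 0.11) and BCL2L11 (1.05 ± 0.07) rose. The largest single rises were those of GBP2 (3.81 ± 0.12), CLIC3 (3.76 ± 0.13), YPEL3 (3.70 ± 0.08), TMT1A (3.65 ± 0.19), AQP3 (3.43 ± 0.19), TMEM255A (3.37 ± 0.15) and PSG3 (3.25 ± 0.14). Further large falls were those of the replication-coupled ubiquitin ligase subunit DTL (-3.11 ± 0.20), the exonuclease EXO1 (-3.01 ± 0.21) and CDCA7 (-2.77 ± 0.11).

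What each drug added to the other was read from the combination against the single drugs. Adding alpelisib to osimertinib changed 2643 genes, 1178 higher and 1465 lower, and with arrays scaled by loess the split was 1342 and 1386, with centring 1013 and 1790. FOXO targets and PI3K feedback genes rose in 11 of 19 cases (12 over the list alone; camera adjusted p = 1.9e-10; adjusted p = 0.227 with an estimated correlation). PDK4 rose by 1.57 ± 0.27 and IRS2 by 1.37 ± 0.12. G1/S genes fell in 18 of 21 cases by either adjustment (camera adjusted p = 6.3e-13) and G2/M genes in 19 of 20 (20 over the list alone; camera adjusted p = 1.4e-12), with an adjusted p = 0.301 for both lists with an estimated correlation. MCM10 changed by -1.43 ± 0.19, the chromatin factor UHRF1 by -1.22 ± 0.10 and PLK1 by -1.06 ± 0.15. THSD7A (1.83 ± 0.15), EFCAB13-DT (1.80 ± 0.17), ATG9B (1.63 ± 0.14) and TCIM (1.58 ± 0.29) were the other leading rises. TCIM was not called without the osimertinib array with L-histidinol (1.01), nor PDK4 without the osimertinib array (1.26). DUSP6 differed by 0.47 ± 0.18 and was not called (adjusted p = 0.12), but was without either vehicle array and with all 2-way terms. This comparison leaned on single arrays: 508 genes were called without the osimertinib array with L-histidinol, 719 without the osimertinib array and 1051 without the combination array. Of the G2/M genes 2 were called lower without the osimertinib array with L-histidinol, which left 7 FOXO targets higher, and of the G1/S genes 7 without the osimertinib array.

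Adding osimertinib to alpelisib changed 5735 genes, 2897 higher and 2838 lower, and 533 of them at least 2-fold. With arrays centred the split was 2428 higher and 3400 lower, and 2968 genes were called without the alpelisib array and 3692 without its L-histidinol partner. ERK output genes fell in 15 of 18 cases by either adjustment (camera adjusted p = 2.3e-13; adjusted p = 0.145 with an estimated correlation), DUSP6 by 3.73, FOSL1 by 3.25 and ETV5 by 3.08 on the log2 scale. All 21 G1/S genes fell by either adjustment (camera adjusted p = 1.7e-18; adjusted p = 0.264 with an estimated correlation), and interferon response genes rose in 16 of 17 cases (17 over the list alone; camera adjusted p = 3.1e-11; adjusted p = 0.264 with an estimated correlation). OAS2 rose by 2.10 ± 0.19. CLIC3 (2.33 ± 0.13), TP53INP1 (2.25 ± 0.12) and GBP2 (2.15 ± 0.12) were the largest rises.

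Set directly against alpelisib, osimertinib gave 2185 called genes, 1096 higher and 1089 lower. ERK output genes were lower with osimertinib in 17 of 18 cases by either adjustment (camera adjusted p = 2.4e-26; adjusted p = 0.052 with an estimated correlation), DUSP6 by -4.21 ± 0.18. So were all 21 G1/S genes by either adjustment (camera adjusted p = 5.0e-20; adjusted p = 0.456 with an estimated correlation). Interferon response genes were higher with osimertinib in 12 of 17 cases (15 over the list alone; camera adjusted p = 2.2e-09; adjusted p = 0.456 with an estimated correlation). The FOXO list was not called between the drugs (camera adjusted p = 0.235), with IRS2 lower by -0.54 ± 0.12 with osimertinib, a call lost without the variance trend, without the osimertinib array (-0.35) and without either alpelisib array. MAP7D2 (2.23 ± 0.09) and the lectin CLEC7A (2.04 ± 0.12) were higher with osimertinib. Without the alpelisib array 452 genes were called, without the osimertinib array with L-histidinol 606, without the osimertinib array 680 and without the alpelisib array with L-histidinol 806. Without the alpelisib array 8 G1/S genes were called lower, and without the osimertinib array with L-histidinol 5 interferon response genes were called higher. The centred split was 943 higher and 1303 lower.

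Whether the combination exceeded the sum of the single drugs was tested as an interaction. limma called 6 genes, all below the sum, against 1748 genes at an unadjusted p under 0.05. They were the oxygen carrier myoglobin, MB (-1.12 ± 0.12), CCN5 (-0.95 ± 0.09), the ubiquitin ligase FBXO32 (-0.94 ± 0.09), AFAP1L2 (-0.92 ± 0.12), SMIM14 (-0.86 ± 0.09) and NME1, the last named only because the count was small. None of the 6 was called with the mean of probe sets, without the variance trend or when any 1 of the 4 arrays with a single drug was left out. With all arrays no member of the fixed lists was called over all genes. With 1 array left out up to 8 G1/S genes and 1 G2/M gene were called below the sum and 1 interferon response gene above it. Over the list alone 7 of 21 G1/S genes were called below the sum, and the list median was -0.54 (camera adjusted p = 4.8e-06; adjusted p = 0.655 with an estimated correlation). G2/M genes had a median of -0.38 (camera adjusted p = 3.05e-05; adjusted p = 0.655 with an estimated correlation) with none called. Interferon response genes had a median of 0.42 with 7 of 17 called above the sum over the list alone (camera adjusted p = 6.7e-06; adjusted p = 0.600 with an estimated correlation). The G1/S and G2/M lists fell with each drug, so below the sum means a larger fall than additive for them. CDK1 differed from the sum by -0.57 ± 0.21 (adjusted p = 0.45) and UHRF1 by -0.88 ± 0.14 (adjusted p = 0.084). UHRF1 was called without the L-histidinol arrays of vehicle (-1.02) and of the combination (-0.99), each left out alone. In simulations of this interaction 0%, 75% and 100% of departures of 0.5, 1 and 2 log2 units were recovered.

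The L-histidinol response was then compared between drug backgrounds. Across genes, the response in vehicle correlated with that in osimertinib at r = 0.547, in alpelisib at r = 0.591 and in the combination at r = 0.359, where the pairs share no array and genes are not independent replicates. The ISR list had a median response of 1.14 in vehicle, 0.85 in osimertinib, 0.82 in alpelisib and 0.54 in the combination, each above all of 10000 random lists of matched expression. ASNS rose by 2.59 in vehicle, 1.98 in osimertinib, 1.97 in alpelisib and 1.54 in the combination, and CHAC1 by 2.41, 1.47, 1.90 and 1.32 in the same order. Amino acid synthesis genes had medians of 0.99, 0.80, 0.85 and 0.78 and aminoacyl-tRNA synthetases of 0.54, 0.59, 0.53 and 0.42. For G2/M and mitosis genes the medians were -0.42 in vehicle and -0.21 in alpelisib, but 0.18 in osimertinib and 0.25 in the combination, and 0, 1, 16 and 18 of the 20 members lay above 0. Interferon response genes had medians of 0.63, 0.35, 0.17 and 0.06 in vehicle, osimertinib, alpelisib and the combination, the last at the 49.9th percentile of random lists. G1/S and DNA replication genes had medians of -0.39, -0.63, -0.59 and -0.03 in the same order. In the combination 8 of their 21 members lay above 0.

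**Figure D2:**
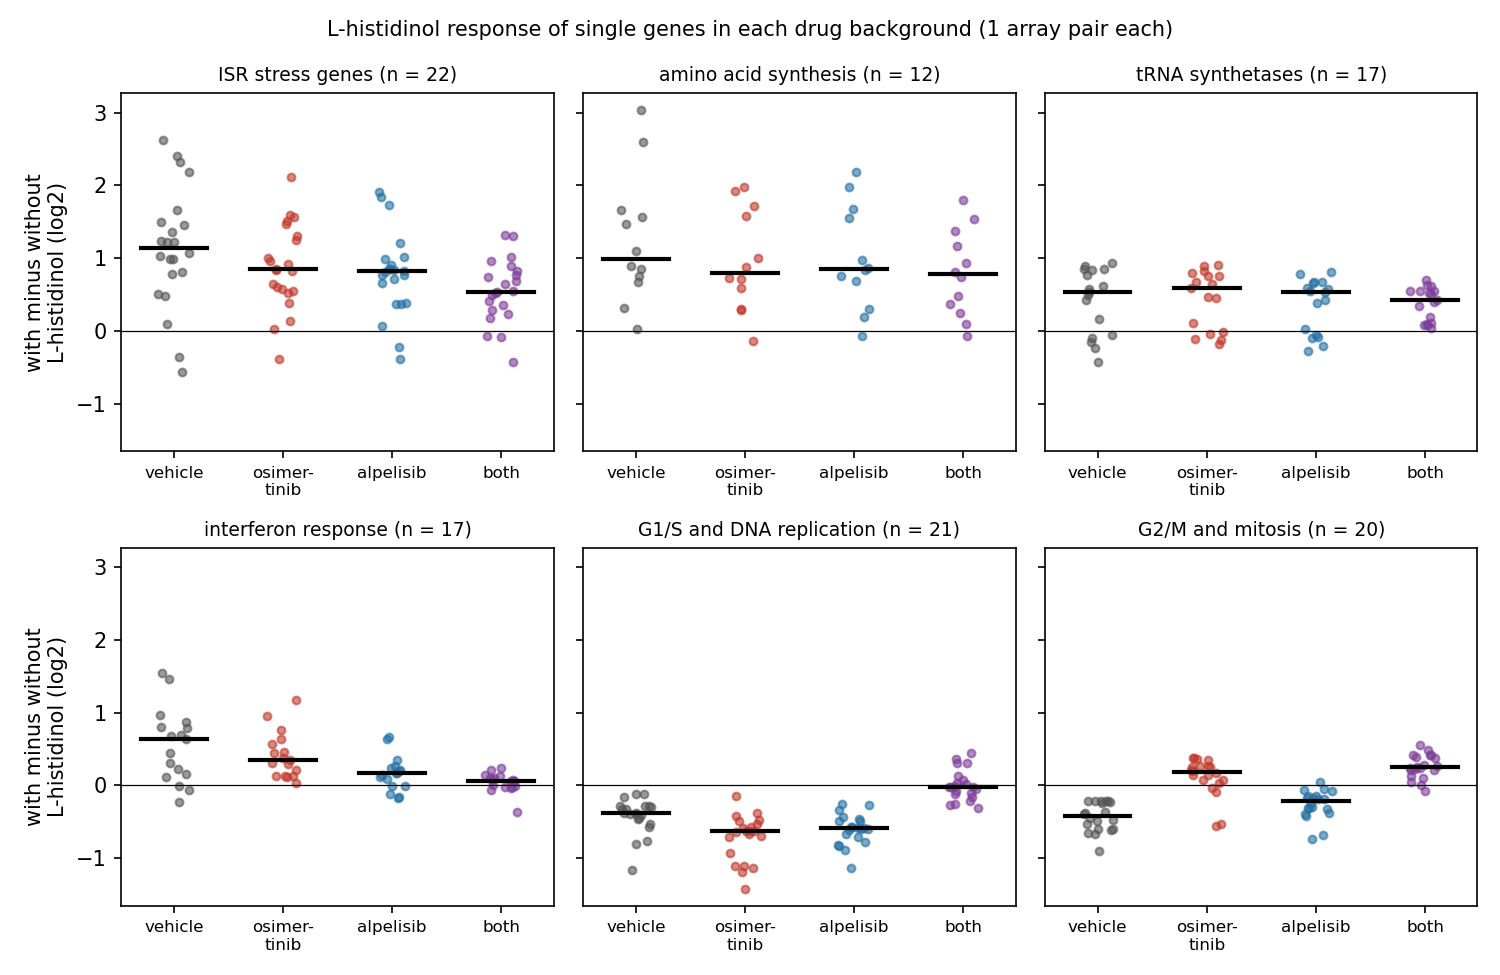
L-histidinol response of each measured member of 6 fixed lists in each drug background, as the log2 difference of 1 array with and 1 array without L-histidinol, with black bars at the medians. The ISR medians descend from 1.14 in vehicle to 0.54 with both drugs, and the G2/M medians lie at -0.42 and -0.21 without osimertinib and at 0.18 and 0.25 with it.

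The interaction of L-histidinol with osimertinib called 896 genes, 576 with a higher and 320 with a lower response in the presence of osimertinib. This test had 1 residual degree of freedom, and in simulations 37.5%, 22.7% and 9.91% of its calls were false at true changes of 0.5, 1 and 2 log2 units. The simulated fits estimated priors of 27.2, 21.4 and 16.0 degrees of freedom, against 103 in the real fit. The simulated shares therefore do not carry over to the 896 calls. With the prior degrees of freedom held at those of the additive fit 81 genes were called, 55 higher and 26 lower, and the single genes named for this interaction were called with either prior. All 20 G2/M and mitosis genes had a higher response (20 over the list alone, 14 with the held prior), median 0.52 (camera adjusted p = 5.0e-18; adjusted p = 0.598 with an estimated correlation). Among them were the proliferation marker MKI67 (0.65 ± 0.09), CDK1 (0.62 ± 0.08) and the mitotic kinesin CENPE (0.69 ± 0.10). ISR stress genes had a lower response in 9 of 22 cases (11 over the list alone, 3 with the held prior), median -0.17 (camera adjusted p = 6.6e-05; adjusted p = 0.598 with an estimated correlation). The response of NUPR1 differed by -0.93 ± 0.08 and that of KLHL24 by -0.66 ± 0.10. ASNS had a lower response by -0.52 ± 0.07, ALDH1L2 by -1.06 ± 0.14, EGR1 by -1.06 ± 0.13 and CCND1 by -0.74 ± 0.09. With the mean of probe sets ASNS (-0.44, adjusted p = 0.0939), ALDH1L2 (-0.63, adjusted p = 0.057), KLHL24 (-0.48, adjusted p = 0.0503) and PDE4B (0.53, adjusted p = 0.158) were not called, and without the marked probe sets ASNS was not (-0.36, adjusted p = 0.45). None of the genes named for this interaction was called without the variance trend. With the other interaction term dropped 3 genes were called in all, 1 higher and 2 lower, and of the genes named here EGR1 and CCND1 were kept. PDE4B (1.18 ± 0.19) and GALNT15 (0.98 ± 0.13) had the largest higher responses called with either prior. Scaling moved the split to 255 higher and 188 lower after centring and to 118 and 123 after loess.

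The interaction of L-histidinol with alpelisib called 278 genes, 155 with a higher and 123 with a lower response, and 17 with the held prior, 5 higher and 12 lower. After centring the split was 46 and 66 and after loess 15 and 35. Interferon response genes had a lower response with alpelisib in 11 of 17 cases (12 over the list alone, 3 with the held prior), median -0.33 (camera adjusted p = 6.1e-11; adjusted p = 0.724 with an estimated correlation), including IFI44L (-0.92 ± 0.10) and MX1 (-0.84 ± 0.09). ISR stress genes had a lower response in 7 of 22 cases (over the list alone 14 lower and 1 higher, 3 lower with the held prior), median -0.28 (camera adjusted p = 4.4e-10; adjusted p = 0.724 with an estimated correlation). The activin subunit INHBE (-1.56 ± 0.21) led them, GDF15 had a response lower by 1.00 ± 0.09, and NUPR1 (-0.68 ± 0.08) and ASNS (-0.53 ± 0.07) were also called with either prior. Without the marked probe sets GDF15 (-0.00085, adjusted p = 0.999) and ASNS (-0.19, adjusted p = 0.87) were not called, nor were they with the mean of probe sets (-0.45 for GDF15 and -0.36 for ASNS). Outside the lists LAMP3 (-1.07 ± 0.13) and the ISR-associated NIBAN1 (-0.95 ± 0.09) had lower responses, and the vitamin D hydroxylase CYP24A1 (0.88 ± 0.09) and MGP (0.88 ± 0.11) higher ones, MGP not being called in either of these settings. No gene named for this interaction was called without the variance trend or with the other interaction term dropped.

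**Figure D3:**
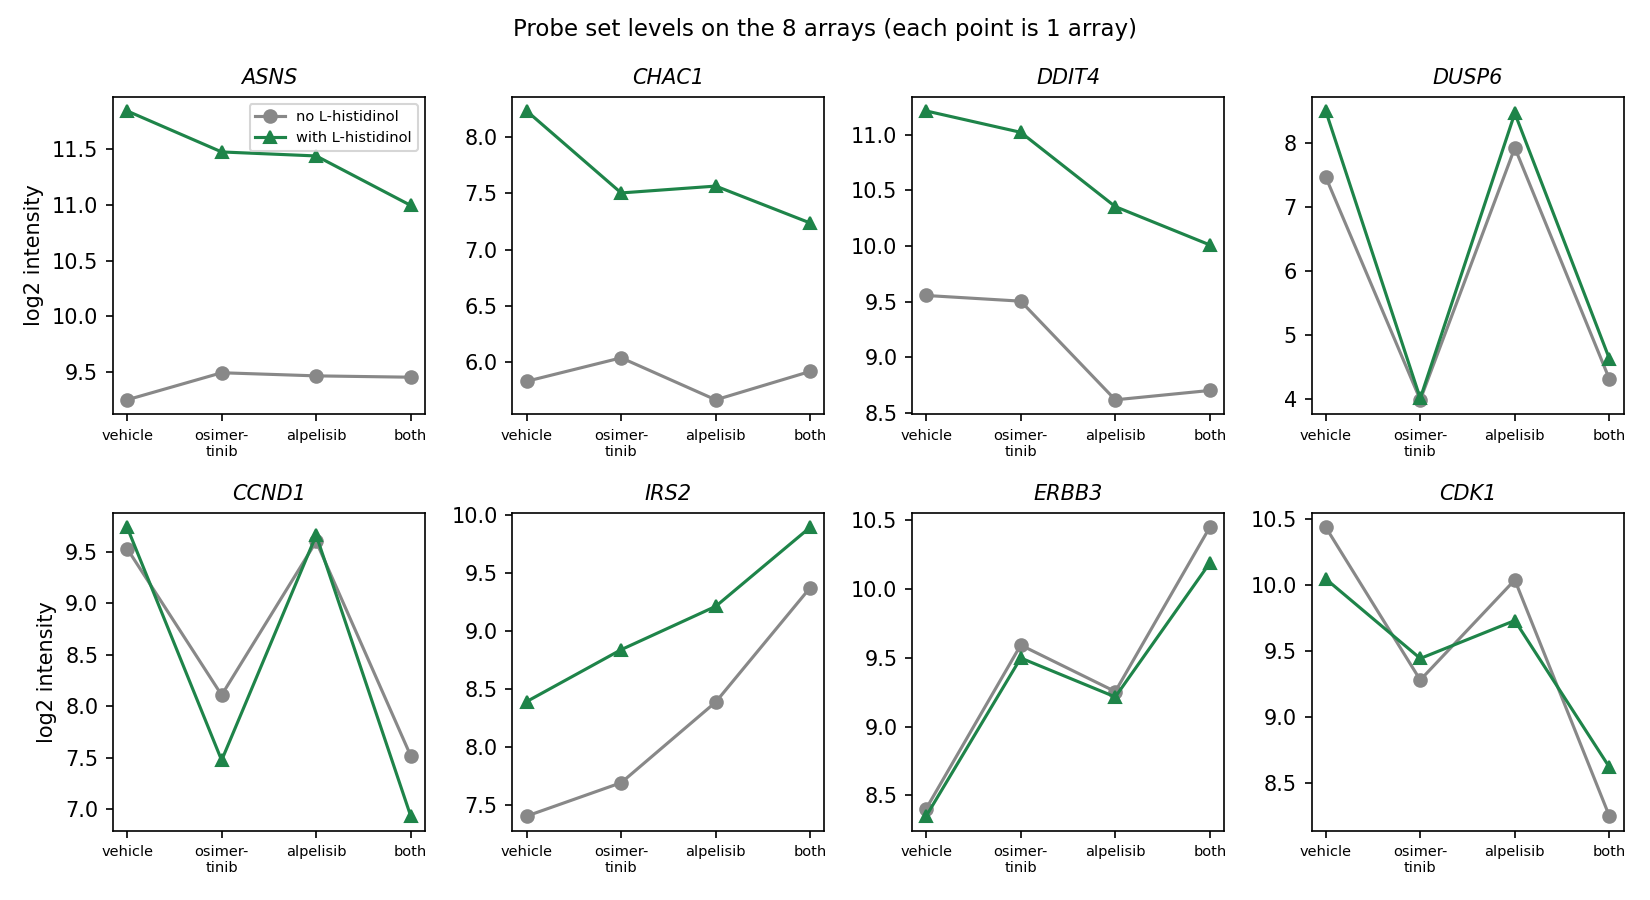
Log2 intensity of the probe sets of ASNS, CHAC1, DDIT4, DUSP6, CCND1, IRS2, ERBB3 and CDK1 on each of the 8 arrays, by drug treatment on the horizontal axis, without (grey circles) and with (green triangles) L-histidinol. Each point is 1 array and has no error. The ASNS curves stand apart in every drug treatment, by 2.59 in vehicle and 1.54 with both drugs, DUSP6 is low only on the 4 arrays with osimertinib, and the CDK1 curves cross between the arrays without and with osimertinib.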

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

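All tests of explanations in this part were chosen only after the results had been seen, whereas the interaction tests themselves were planned. The spreads given with them come from resampling genes or from random gene lists of matched expression. They hold no variation between arrays. Interactions are listed because an effect differed between groups by a test of the difference itself. The interaction of osimertinib with alpelisib called 6 genes and 7 gene lists, that of L-histidinol with osimertinib 896 genes and 9 lists, and that of L-histidinol with alpelisib 278 genes and 8 lists. Camera with an estimated correlation called 0 lists in each of these interactions. Signal was also found in data outside the gene tests. Among 13522 probe sets without a single gene name, 780 were called for L-histidinol (484 higher and 296 lower) and 1894 for the combination against vehicle (1019 higher and 875 lower). The control probe set for the 5′ part of 28S ribosomal RNA had an intensity of 5796 on the array with both drugs and L-histidinol, against 2328 to 3713 on the other 7 arrays.

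The grouping of arrays was checked by relabelling them. Of the 35 splits of the arrays into 4 and 4, 32 could be fitted with drug as a block, and 1 of the 32, the real one, called 4069 genes or more, while the highest other split called 0. The other splits leave at least part of the L-histidinol effect in the residual, which holds their counts low. This comparison therefore cannot exclude an arbitrary grouping for the gene count. For the gene lists 6 of 32 splits called at least the real 11, and the highest other split called 13. Some of these splits separate L-histidinol within part of the drug treatments and so hold its effect. They are no reference for arbitrary groupings, and no conclusion is drawn for the number of lists.

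The L-histidinol response of ISR stress genes was smaller with the drugs, with a median of 0.54 in the combination against 1.14 in vehicle. Set against vehicle, the list median with both drugs was 0.22 without L-histidinol and -0.19 with it. Of the 22 members, 13 and 9 lay above 0 in these differences between single arrays. The smaller response thus went with both shifts of the list median, and neither shift has a replicate check. Saturation of bright probe sets forbids a deficit among dim members, but in the 17 members below log2 10 the deficit was 0.404 with a spread of 0.229, within 2 spreads of 0. A weaker response of all responding genes was tested on 261 other raised genes, whose ratio of combination to vehicle response was 0.624 (spread 0.0939) against 0.472 for the ISR genes. A single odd array was tested by the 2 steps from vehicle to single drugs and on to the combination, the smaller being 0.199 (spread 0.116) and the other 0.270. None of the 3 values cleared its bound, so these explanations cannot be told apart from an effect of the drugs on the stress response.

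The L-histidinol response of G2/M and mitosis genes differed in sign with osimertinib. Values at the floor of the array are argued against by a median level of 8.66 (standard deviation 1.16 over members) on the 4 arrays with osimertinib, above the upper quartile of all genes at 8.01. An odd vehicle array alone is argued against by the same difference without any vehicle array, 0.519 between the combination and alpelisib. Its spread of 0.0437 is over genes, so an odd array among those of the combination and alpelisib is not addressed. Scaling is argued against by medians of 0.514 after centring and 0.493 (spread 0.0349) after loess. A hypothesis left open is that osimertinib, which lowers these transcripts, may change how the cell cycle answers to L-histidinol, but it was found and tested on the same 8 arrays. Differences between dishes, such as culture density, were not tested.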

How the results depend on the processing

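The held prior, and for the gene lists the dropped interaction term, were chosen only after the results had been seen, and all other alternatives were planned. L-histidinol was compared within pairs of arrays that share a drug treatment. No paired analysis was possible because of shared replicate numbers, since each condition had a single array. Counts called stayed within 1.5 times the main count except for those given here, and the cause was not tested unless stated. For L-histidinol 6476 genes were called with all 2-way terms and 58 without the drug block, which leaves the drug effects in the residual. For alpelisib 1222 were called with the mean of probe sets, 779 without the variance trend, 5022 with all 2-way terms and 4039 with the drug averaged over both states of the other drug. For the combination against osimertinib the first 3 of these gave 1646, 1017 and 5194. For osimertinib against alpelisib 1042 were called without the trend and 4670 with all 2-way terms. For the interaction of the drugs 0 were called with the mean of probe sets, 0 without the trend and 13 with the robust prior.

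The interactions of L-histidinol depended most on the processing. With osimertinib 139 genes were called with the mean of probe sets, 594 without probe sets marked for possible cross-hybridization, 443 after centring, 241 after loess, 0 without the trend, 3 with the other term dropped and 81 with the held prior. With alpelisib these were 19 with the mean, 112 after centring, 50 after loess, 0 without the trend, 0 with the other term dropped and 17 with the held prior. Camera with an estimated correlation called 0 lists in each of the 10 comparisons. It tests at 3 or 1 residual degrees of freedom here, so this outcome says little for or against the lists. fry called 6 lists for alpelisib, 5 for the combination against osimertinib, 3 for osimertinib against alpelisib, 0 for the interaction of the drugs, 0 for L-histidinol with osimertinib and 1 for L-histidinol with alpelisib.

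Leaving out 1 array at a time assumes that its lone partner varies like the others. The genes called ranged from 2160 to 4056 for L-histidinol (2160 without the osimertinib array, 2168 without its L-histidinol partner, 2403 and 2389 without those of alpelisib), from 3755 (without the osimertinib array) to 6375 for osimertinib, and from 175 to 3009 for alpelisib (600, 175 and 1171 without the alpelisib, alpelisib with L-histidinol and vehicle arrays). They ranged from 6660 to 7694 for the combination, 508 to 3271 for the combination against osimertinib, 2968 to 6282 against alpelisib, 452 to 2751 for osimertinib against alpelisib and 0 to 68 for the interaction of the drugs. That last count was 0 without either osimertinib or either alpelisib array, 11 without the combination array, 15 without the vehicle array with L-histidinol and 68 without the combination array with L-histidinol. Lists called ranged from 11 to 14, 9 to 12, 9 to 11, 11 to 12, 12 to 13, 10 to 14, 5 to 9 and 3 to 10 in the same order, the 3 arising without the combination array and without the vehicle array with L-histidinol. For the interactions of L-histidinol this was not run, since no residual degree of freedom remains.

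Without probe sets marked for possible cross-hybridization, where another probe set stands for the gene, 4 printed values of called genes turned in sign. They were IDI1 (0.058) and SQSTM1 (-0.0024) for L-histidinol and TMT1A for osimertinib (-0.044) and the combination (-0.025). The same setting ended further calls. For L-histidinol it left ASNS at 0.08, GDF15 at 0.12, MGP at -0.09 and GINS2 at -0.07, for osimertinib NRG1 at -0.13, for alpelisib FN1 at 0.45, for the interaction of L-histidinol with osimertinib ASNS at -0.36, and for that with alpelisib ASNS at -0.19, GDF15 at -0.00085 and MGP at 0.63. Printed genes had 513 values for L-histidinol under the alternatives other than leaving out an array. Of these, 462 were kept, meaning the same side of the threshold and, for genes called in the main fit, the same direction. Another 49 fell short of the threshold. A turn in sign of a gene not called in the main fit counted as kept. For osimertinib 389 of 393 were kept, for alpelisib 295 of 313 and for the combination 324 of 332. The mean of probe sets brought many values that kept their call closer to 0, such as TP53INP1 with the combination to 1.17. Centring moved the median of all genes to -0.13 for the combination and -0.09 for osimertinib, so splits into higher and lower genes rest on the authors' normalization. Dim probe sets limit what can be seen, as 11627 of 19775 genes had a mean log2 of at least 5.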

Other observations

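The gene families here and the tests on them were chosen only after the results had been seen, and the correlations were planned. Only family members with a mean log2 of at least 5 over the arrays were counted, and counts with 1 array left out are the lowest over the arrays. All 4 such YPEL genes, a family linked to growth arrest that includes YPEL3, rose with osimertinib, with alpelisib and with the combination, with medians of 1.97, 1.36 and 2.45 on the log2 scale, and none was called for L-histidinol (median 0.06). These counts held after centring and after loess, and 3 were called with osimertinib and with alpelisib when 1 array was left out. Guanylate-binding proteins, interferon-inducible GTPases that include GBP2, rose in 3 of 4 cases with each drug treatment, though in 2 of 4 after centring for alpelisib and for the combination, in 2 after loess for the combination, and in 2 with each when 1 array was left out. Pregnancy-specific glycoproteins, placental surface proteins that include PSG3, rose in 7 of 7 cases with each drug treatment (medians 1.96, 1.05 and 2.79) and fell in 7 of 7 with L-histidinol (median -0.68) under every scaling, though with alpelisib 4 were called when 1 array was left out. Their sequences are nearly identical, so probe sets of this family do not count as independent.

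Core histone genes, whose polyadenylated transcripts the 3′ assay reads, rose in 10 of 17 cases with osimertinib (8 after centring), in 14 with the combination (12 after centring), in 8 with L-histidinol (5 when 1 array was left out) and in 2 with alpelisib (0 when 1 array was left out). Metallothioneins, metal-binding proteins, rose in 7 of 7 cases with alpelisib, though in 2 when 1 array was left out, and in 7 of 7 with the combination (4 after centring, and 4 when 1 array was left out). Whether probe sets of the histone and metallothionein families share signal was not tested, so their members are not taken as independent. The osimertinib response without L-histidinol correlated with that in its presence at r = 0.789 across 19775 genes, the alpelisib response at r = 0.567 and the combination response at r = 0.865, between array pairs that share no array. The mean log2 of the poly-A spike controls was 5.62 on the alpelisib array without L-histidinol and 6.16 to 6.41 on the others.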
